A study of Homo sapiens with 12 samples.

How the data were processed

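HEK293T is an established human embryonic kidney cell line. Its total RNA was treated with CMC, a carbodiimide that after alkaline treatment stays mainly on pseudouridine, the C-glycoside isomer of uridine, or was left without CMC. Reverse transcriptase can read a CMC-modified base as a deletion, as another base or as an end of the cDNA. The series holds 12 libraries. 6 are transcript libraries read over 18S and 28S rRNA, 3 with CMC (CMC+) and 3 without (CMC-). The other 6 are RT-PCR amplicons of 18S rRNA, EEF1A1 mRNA and MALAT1 RNA, each with 1 CMC+ and 1 CMC- library. Groups, replicate numbers and the target positions of the amplicons were taken from the sample titles.

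Per the labels' protocols, RNA was extracted with TRIzol, the transcript libraries were made by ligating adapters to RNA fragments and then to cDNA, and for the amplicons RNA was fragmented, CMC-reacted or mock-treated and reverse transcribed, and libraries were made from the RT-PCR products. Both kinds were sequenced as read pairs on the same Illumina model. Per the submitters' processing notes, Bowtie2 and the hg19 build were used. Their role, the aligner settings, read filters and duplicate removal are not given in the sources used here. Per the file headers, positions are numbered along RefSeq transcripts from the 5′ end, and no chromosome coordinates were used here. The annotation of pseudouridine at 98 rRNA positions is a column of the authors' deposited per-sample files. How that annotation was made is not given in the sources used here, so it was not treated as independent of these libraries.

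The authors deposited, per position, counts of all reads and of reads with a deletion, a deletion of a single base, a mismatch or an insertion. Stop rates were deposited by the authors as percent values per library without event counts. The authors also deposited a pooled CMC+ table, of which only the counts of deletion reads were used, and a stop difference per position. At all 6939 positions that difference equalled the mean CMC+ rate minus the mean CMC- rate, set to 0 where negative, within 0.000001. Deletion reads in the authors' pooled table were a median 0.664 of those summed over the 3 CMC+ libraries. Which reads were pooled is not given in the sources used here.

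Median reads per rRNA position were 19225, 24219 and 18988 in CMC+ replicates 1, 2 and 3, and 39495, 39734 and 42200 in CMC- replicates 1, 2 and 3, with a lowest value of 355. At the median depth, 3 counts correspond to a rate between 0.012% and 0.016% in CMC+ libraries and between 0.0071% and 0.0076% in CMC- libraries. Amplicon positions held between 3164034 and 3220409 reads in the 18S rRNA CMC+ library. The other 5 amplicon libraries held between 14416300 and 15000031 reads at every position, and the reason for such even totals is not given in the sources used here. Reads from PCR without molecular identifiers are not independent molecules, so the intervals given for amplicons cover counting error only.

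Rates were computed as events divided by reads, in percent. The test for deletions and mismatches was limma with a trended prior variance on log2((events + 0.5)/(other reads + 0.5)), so that a log2 change is a log2 odds ratio, CMC+ over CMC-. A position was tested with at least 50 reads in every library and at least 1 event. For stops the planned test on counts was replaced by its fallback, limma on log2(rate + 0.1 percentage points), because that table gives rates alone, and a log2 change there understates changes of low rates. The limma p-values were two-sided and adjusted by the Benjamini-Hochberg method over the positions tested, and a position was called at an adjusted p under 0.05. Neighbouring positions share reads, so positions are not independent replicates. The labels do not say whether replicates came from separate cultures, and p-values measure the spread between these libraries only. Fisher's exact test, two-sided, was used for bases and lists, and permutation tests for the separation of annotated positions (two-sided) and for misread bases (one-sided), all without adjustment. Amplicon shares have exact Clopper-Pearson 95% intervals and no test.

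The named positions were fixed before the data were examined as the positions in the labels, the 12 called positions with the greatest rise in stop rate and in deletion rate for which every CMC+ library lay above every CMC- library, the 5 greatest falls of each kind in the mirrored sense, the 5 greatest rises in mismatch rate, and in each amplicon the 3 greatest further rises in deletion and in mismatch. Also fixed then were a list of 34 pseudouridines of 18S rRNA, a list of 44 of 28S rRNA and a list of 7 other modified 18S positions. All 34 members of the 18S list and 43 of the 28S list fell on T in the files, above the 90% required, and the remaining 28S member, on another base, was left out. Other positions named in the text were chosen after their values were seen, and the separation of annotated positions from other T by each readout and the comparison with the authors' annotation were added after the data were seen.

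Each test was first run on simulated data with 100 positions changed by 1 and 100 by 2 on the log2 scale. For deletions, 14% and 61% of those positions were called. For mismatches 99% and 100% were called, and for stops 98% and 99%. Unchanged positions made up 5.06% of the deletion calls, 5.69% of the mismatch calls and 5.29% of the stop calls. Counts of the replicates of a group differed by more than sampling noise in every pair, with chi-square per position between 1.11 and 2.04 for deletions and between 1.38 and 7.30 for mismatches. Repeat libraries of one RNA could differ as much, so this does not show that the replicates were separate samples, and each library was counted as labelled. Alternatives covered coverage minimums, added constants, a quasi-binomial model, edgeR, no variance trend, a replicate block, each replicate left out, a minimum difference, and the placement of deletions in runs of identical bases. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.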

Results

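Reads with a deletion, a mismatch, an insertion or a cDNA end were counted at 6939 positions of HEK293T rRNA, 1869 in 18S and 5070 in 28S, in 3 CMC+ and 3 CMC- libraries. 98 of these positions, 38 in 18S and 60 in 28S, carry the authors' annotation as pseudouridine, and all of them are T in the reference. The series concerns reading pseudouridine at chosen loci from RT-PCR products, and 3 amplicons cover 18S rRNA positions 1045 and 1056, EEF1A1 position 519 and MALAT1 position 5590. EEF1A1 encodes a translation elongation factor and MALAT1 is a long noncoding RNA of the nucleus. The amplicon libraries held at least 3164034 reads at every position. Median reads per rRNA position were 20811 ± 2954 (SD, n = 3) in CMC+ and 40476 ± 1498 (SD, n = 3) in CMC- libraries.

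The first question was which rRNA positions reverse transcriptase skips after CMC. At the annotated pseudouridines the median deletion rate was 16.6% ± 0.48 (SD, n = 3) with CMC and 0.088% ± 0.0080 (SD, n = 3) without. Other T positions had a median of 1.11% ± 0.064 with CMC and 0.039% ± 0.0015 without (SD, n = 3). The CMC+ medians were 0.956% ± 0.038 at A, 0.553% ± 0.0061 at C and 0.860% ± 0.0013 at G (SD, n = 3), against 0.037%, 0.041% and 0.042% without CMC. Most positions of every class of base rose in deletion, and annotated pseudouridines by the most percentage points, while relative to the general rise described next more C positions were lower than higher. Over all reads and positions the deletion rate was 1.84% ± 0.025 in CMC+ and 0.109% ± 0.0031 in CMC- libraries (SD, n = 3).

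With limma, 6625 of 6920 tested positions were called higher in CMC+ and 57 lower, with a median log2 odds ratio of 4.27 over all positions. With each library's median subtracted, an alternative chosen after seeing the data, 2281 were called higher and 2416 lower. Relative to that general rise, on the log2 scale, 94 of the 98 annotated pseudouridines were higher, 28S 4299 and 5001 were lower, and 18S 218 and 1244 were not called. 28S 4299 and 5001 started from CMC- rates of 0.491% and 0.256%. In percentage points they rose by 2.42 and 1.92, against a median rise of 1.05 at other T. Among other T positions 501 were higher and 199 lower relative to the general rise, and among C positions 398 and 1125. A rise of at least 10 percentage points was called at 196 positions, of which 63 were annotated pseudouridines, 51 other T, 34 A, 31 G and 17 C.

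**Figure D1:**
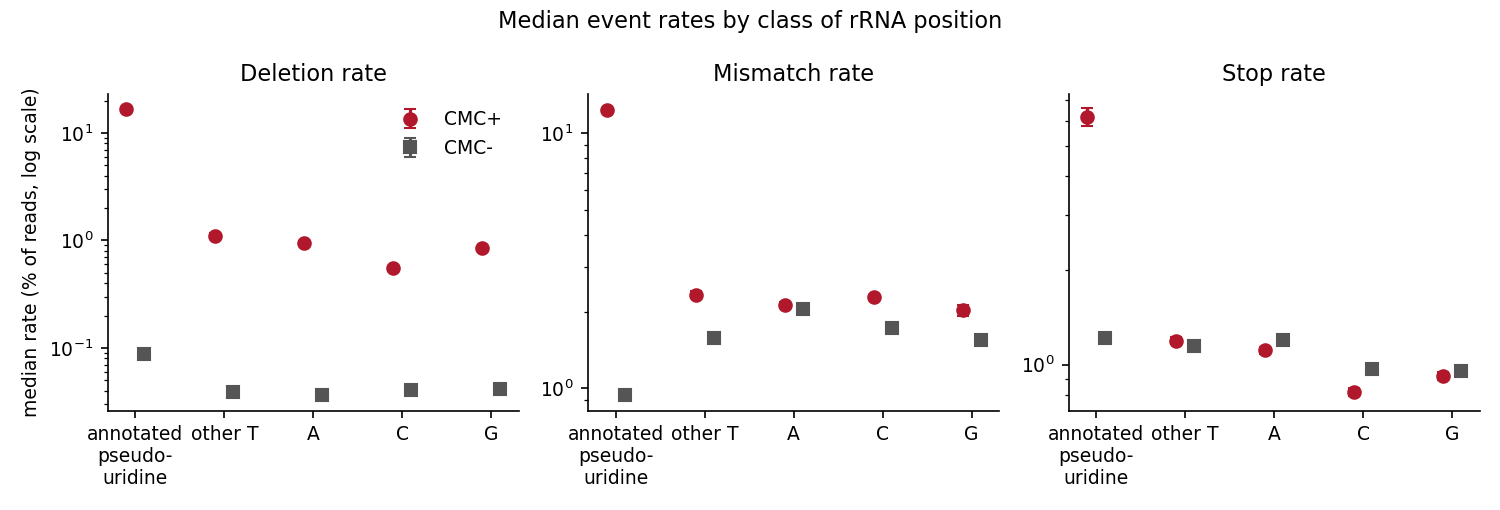
Median deletion, mismatch and stop rate (percent of reads, log scale) over 98 annotated pseudouridines, other T, A, C and G positions of rRNA. Points are means over 3 CMC+ (circles) or 3 CMC- libraries (squares) of the median over positions, and bars are SD; annotated pseudouridines stand at 16.6% deletion with CMC and 0.088% without.

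The 12 greatest rises in deletion lay on an annotated pseudouridine or at most 2 bases 5′ of one. The highest was at 28S 2630, where 55.4% ± 0.70 of CMC+ reads and 0.244% ± 0.017 of CMC- reads (SD, n = 3) had a deletion (log2 odds ratio 8.98, SE 0.072, limma adjusted p = 4.68e-11). That T lies 5′ of the annotated pseudouridine 2632 in the same run of T, which continues past 2632. 18S 571, in the run of pseudouridine 572, reached 54.0% ± 0.49 against 0.220% ± 0.026 (SD, n = 3; log2 odds ratio 9.06, SE 0.090, limma adjusted p = 5.82e-11). Annotated positions 28S 3637, 18S 1081, 28S 3959, 18S 863 and 28S 1779 had CMC+ deletion rates of 52.8% ± 1.6, 49.8% ± 0.58, 46.2% ± 1.2, 44.2% ± 0.51 and 42.7% ± 0.68 (SD, n = 3), each with a CMC- rate between 0.164% and 0.285%. 18S 1002, 28S 4627, 18S 1690 and 28S 4351 are T in the same run as an annotated pseudouridine and reached 47.9%, 47.5%, 46.3% and 43.2%. 28S 4971, an A next to pseudouridine 4972, reached 45.9% ± 0.39 (SD, n = 3). The limma adjusted p of these 12 was at most 3.34e-10. A call in limma and every CMC+ library above every CMC- library were conditions for choosing them, so neither is further support.

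The 5 greatest falls were at positions with many deletions without CMC. 18S 1247, the C before the hypermodified base 1248, fell from 18.4% ± 1.1 to 8.63% ± 0.64 (SD, n = 3; log2 odds ratio -1.25, SE 0.083, limma adjusted p = 7.42e-07), although single-base deletions alone rose there (log2 odds ratio 0.98). 18S 1850, a dimethylated A near the 3′ end, fell from 24.3% ± 1.8 to 18.8% ± 0.56, and 18S 1848 from 16.4% ± 0.24 to 11.2% ± 0.22 (SD, n = 3). 28S 4798 went from 72.1% ± 1.5 to 67.7% ± 0.32 and 28S 2207 from 10.7% ± 0.82 to 7.16% ± 0.53 (SD, n = 3). The call at 28S 4798 ended when limma was fitted without a variance trend (adjusted p = 0.054).

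**Figure D2:**
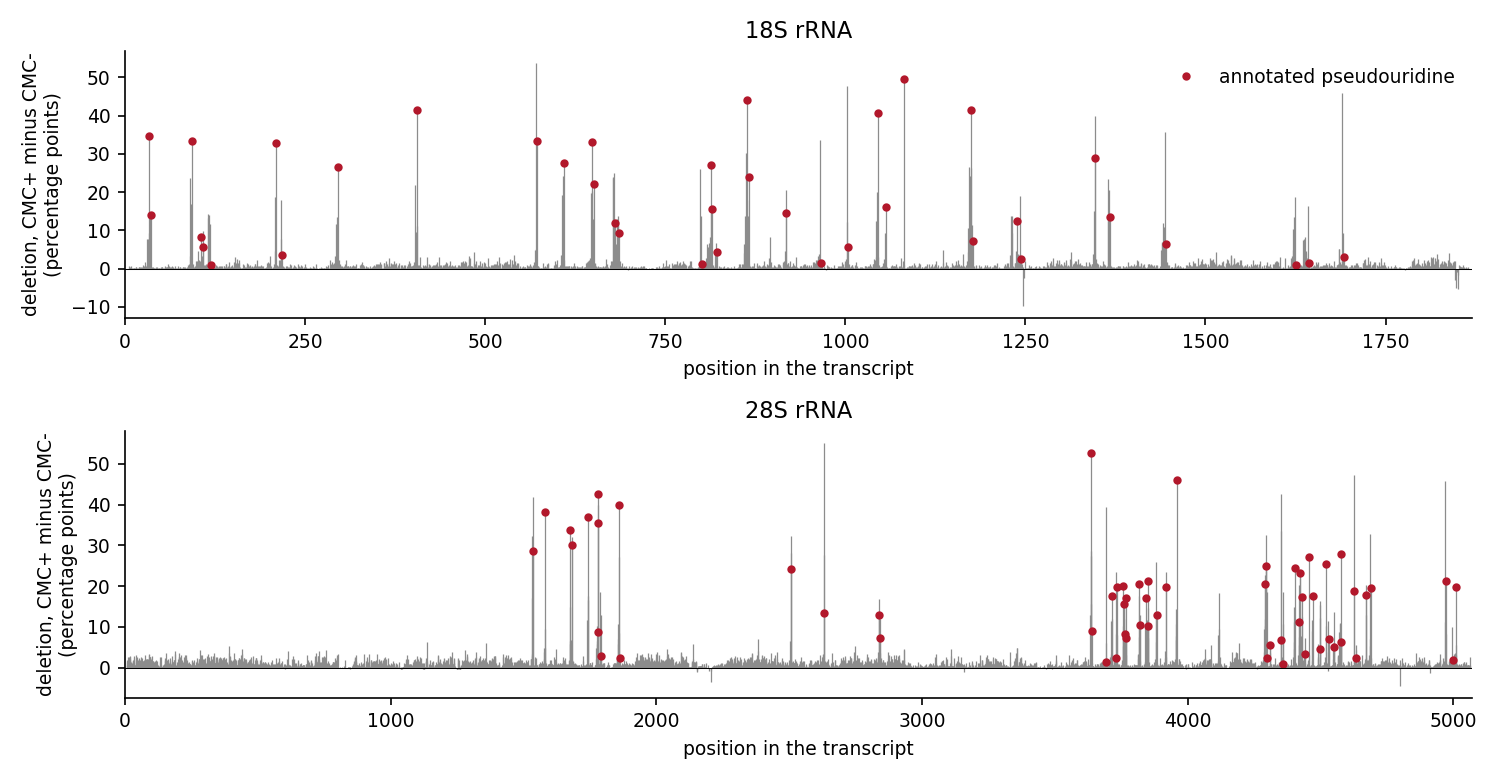
Deletion rate in CMC+ minus CMC- libraries (percentage points, means of 3 libraries each) at each position of 18S and 28S rRNA (grey lines), with annotated pseudouridines as circles. The tallest lines without a circle, 28S 2630 at 55.1 points and 18S 571 at 53.8, stand just 5′ of an annotated pseudouridine, and the fall at 18S 1247 of -9.75 points is the deepest.

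Deletions extended to the 5′ side of annotated pseudouridines. The median CMC+ rate was 13.8% ± 0.35 at 1 base 5′, 10.1% ± 0.14 at 2 bases 5′ and 3.79% ± 0.11 at 3 bases 5′, against 1.22% ± 0.025 at 1 base 3′ (SD, n = 3). Deletions of a single base stayed closer to the site, with 4.68% ± 0.058 at the pseudouridine and 1.35% ± 0.048 at 1 base 5′ (SD, n = 3). Rates also differed by place within a run of T. The 50 annotated pseudouridines that stand alone had a median of 20.8% ± 0.40, the 22 that open a run 12.2% ± 0.42, and the 26 later in a run 6.01% ± 0.15 (SD, n = 3). In that last class single-base deletions had a median of 0.030% ± 0.0046 (SD, n = 3), against 4.89% ± 0.080 in the class that opens a run, and reached 0.412% at 28S 2632. Other T later in a run had a median of 0.718% ± 0.060 and other lone T 1.12% ± 0.056 (SD, n = 3). The 171 other T that open a run had 1.88% ± 0.079 (SD, n = 3). They stood above lone T, the reverse of the order at annotated pseudouridines, so placement on the first base alone does not give that order.

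**Figure D3:**
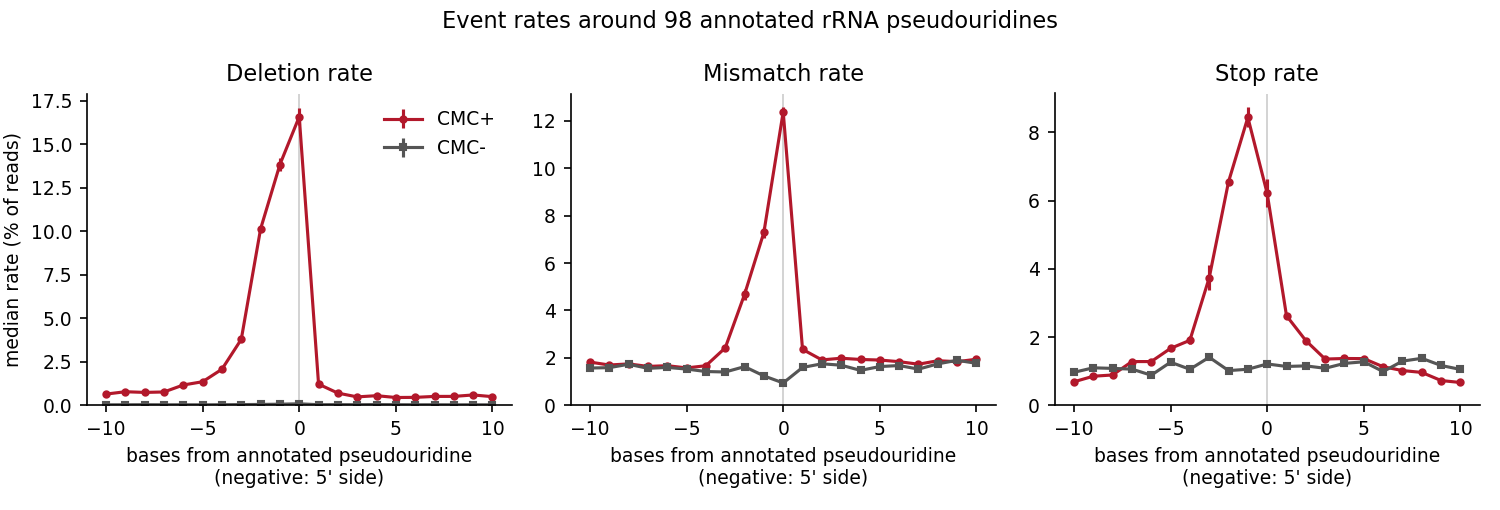
Median deletion, mismatch and stop rate (percent of reads) at each distance in bases from the nearest annotated pseudouridine, negative to the 5′ side, for 3 CMC+ (circles) and 3 CMC- libraries (squares), with SD over libraries as bars. Deletion and mismatch peak at the pseudouridine with 16.6% and 12.4%, and stops as recorded peak 1 base 5′ of it with 8.44%.

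The next question was where CMC changes the base that is read. At annotated pseudouridines the median mismatch rate was 12.4% ± 0.19 with CMC and 0.943% ± 0.012 without (SD, n = 3). At other T it was 2.33% ± 0.075 against 1.57% ± 0.011, and at A 2.11% ± 0.057 against 2.04% ± 0.056 (SD, n = 3). Tested position by position in limma, mismatches rose at all 98 annotated pseudouridines, also with library medians subtracted. The smallest difference was 1.68 points (18S 119) and the greatest 43.8 points (28S 1792). The 18S pseudouridines had a higher CMC+ median, 15.5% ± 0.085, than the 28S ones, 10.6% ± 0.20 (SD, n = 3), while deletion medians were 14.2% ± 0.033 and 17.7% ± 0.75 (SD, n = 3).

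The 5 greatest mismatch rises included 4 annotated pseudouridines. 28S 1792 rose from 2.21% ± 0.19 to 46.0% ± 0.25 (SD, n = 3; log2 odds ratio 5.24, SE 0.077, limma adjusted p = 2.7e-12). 18S 1625 rose from 0.898% ± 0.074 to 42.4% ± 0.35, 28S 2508 from 0.952% ± 0.015 to 39.8% ± 0.49 and 18S 1643 from 1.40% ± 0.064 to 38.3% ± 0.29 (SD, n = 3). The remaining one was 18S 1247, which rose from 4.58% ± 0.33 to 37.2% ± 0.46 (SD, n = 3) while its deletions fell. Over all 6939 positions limma called 4274 higher and 986 lower, with a median log2 odds ratio of 0.38. With library medians subtracted the split was 2367 higher and 2493 lower, and A positions then had 274 higher and 679 lower.

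All 98 annotated pseudouridines rose in both deletion and mismatch, 94 of them in deletion also relative to the general rise, but the sizes differed. Part of this depends on where deletions are placed in runs of T. With deletion taken at the annotated base, it was the largest of the rises in deletion, mismatch and stop at 53 positions, mismatch at 30 and stop at 15. With the largest deletion rise in the run taken instead, a choice made after seeing the data, these counts were 66, 19 and 13. At 10 of them mismatch rose by at least 10 points and deletion by less than 5, but 8 of these, such as 18S 1625, 18S 1643 and 28S 4361, are later in a run, and 2 positions were left with the largest rise in the run. 18S 1692, for example, had 2.95% ± 0.11 deletion (SD, n = 3), while 18S 1690 in its run had 46.3%. 28S 4442, a lone T, had 28.2% ± 0.47 mismatch and 3.41% ± 0.057 deletion (SD, n = 3). The reverse held at 4 positions, 28S 4457, 4403 and 4628 and 18S 681. 28S 4457 had 27.3% ± 1.1 deletion and 5.83% ± 0.17 mismatch (SD, n = 3). Across the 98 positions the rises in mismatch and deletion had Pearson's r = -0.048 and Spearman's rho = 0.057, across the 50 that stand alone r = -0.077 and rho = -0.050, and with the largest deletion rise in the run r = 0.12 and rho = 0.17, a description across positions, which are not independent replicates.

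**Figure D4:**
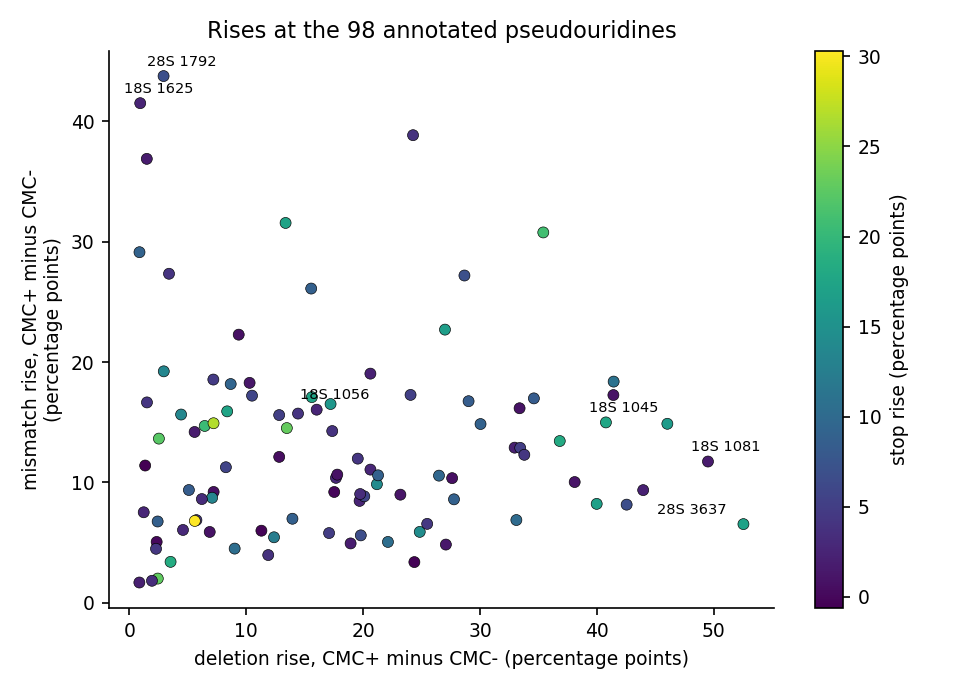
Rise in mismatch against rise in deletion (CMC+ minus CMC-, percentage points, means of 3 libraries each) at each of the 98 annotated pseudouridines, with the rise in stop rate as colour. 18S 1625 and 28S 1792 sit at the upper left with mismatch rises of 41.5 and 43.8 points, where both are later in a run of T, and 28S 3637 and 18S 1081 at the lower right with deletion rises of 52.5 and 49.5 points.

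A further question was at which positions cDNA ends were recorded after CMC. A stop may be recorded next to the modified base, so a recorded position need not be the last base copied. At annotated pseudouridines the median stop rate was 6.22% ± 0.41 with CMC and 1.21% ± 0.028 without (SD, n = 3), and at 1 base 5′ of them 8.44% ± 0.29 and 1.06% ± 0.019 (SD, n = 3). Other T had 1.19% ± 0.032 and 1.14% ± 0.012, and C 0.817% ± 0.025 and 0.965% ± 0.0087 (SD, n = 3). Stops rose at 93 of the 98 annotated positions. They fell at 28S 3695, from 2.31% ± 0.30 to 1.70% ± 0.34 (limma adjusted p = 0.036), and at 28S 4403, from 0.883% ± 0.035 to 0.510% ± 0.18 (limma adjusted p = 0.010), both SD with n = 3. The fall at 28S 3695 was no longer called with library medians subtracted (adjusted p = 0.065). Over 6883 positions limma called 2144 higher and 2355 lower, and 949 and 714 with a difference of at least 1 point. With library medians subtracted the counts were 2388 higher and 2181 lower. The subtraction itself draws the counts toward equal numbers, so this balance does not show a direction of change.

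Of the 12 greatest stop rises, 10 lay 1 or 2 bases 5′ of an annotated pseudouridine and 1 on it, and 5 lay 1 or 2 bases 3′ of one, 4 of which (18S 107, 28S 1861, 3763 and 4298) lay between a pair of annotated positions. 18S 107 rose from 3.07% ± 0.17 to 41.1% ± 0.61 (SD, n = 3; log2 change 3.70, SE 0.072, limma adjusted p = 5.46e-09) and lies 2 bases 5′ of pseudouridine 109, and 18S 108 reached 35.1% ± 0.72. 18S 820 reached 36.9% ± 0.97, 28S 1790 38.8% ± 0.29, 28S 1791 35.7% ± 0.50, 18S 812 35.2% ± 2.4 and 18S 1366 33.9% ± 1.8 (SD, n = 3). 28S 1861, 3763, 4312 and 4298 reached 32.0% ± 0.86, 32.0% ± 0.27, 31.7% ± 1.5 and 30.5% ± 1.2 (SD, n = 3), and of these 4312 is the annotated base itself. 18S 1246, 2 bases 5′ of the hypermodified base 1248 and 2 bases 3′ of pseudouridine 1244, rose from 8.05% ± 1.0 to 38.8% ± 1.3 (SD, n = 3). The 5 greatest falls included 4 positions at the 5′ ends. 28S 2 fell from 47.8% ± 0.78 to 35.0% ± 2.3 (SD, n = 3). 18S 1, 2 and 4 had 18.7% ± 1.2, 6.37% ± 0.29 and 8.72% ± 1.7 with CMC against 30.5% ± 0.77, 14.5% ± 0.84 and 20.4% ± 0.87 without (SD, n = 3). The remaining one, 28S 3501, lies far from the 5′ end and fell from 13.3% ± 0.74 to 3.39% ± 0.89 (SD, n = 3).

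Each readout was then set against the reference base. T made up 16.6% of the tested positions and 21.1% of those called higher for mismatch (Fisher's exact odds ratio 2.52, two-sided p = 6.29e-38), 23.6% for stop (p = 6.25e-25) and 17.1% for deletion (odds ratio 4.15, p = 3.66e-10). Nearly all positions were called higher for deletion, so its odds ratio rests on the few that were not, 14 T and 281 others. It is thus no sign of a stronger preference for T than in mismatch. The deletion odds ratio was also 4.15 for the base 1 position 3′. It was 2.60 with library medians subtracted or a rise of at least 1 point required, both chosen after seeing the data. Among calls with a rise of at least 10 points, a limit added after seeing the data, T made up 75.8% for mismatch, 58.2% for deletion and 42.7% for stop. For stops of that size the base 1 position 3′ of the recorded one was T in 56.3%. Positions are not independent replicates, so these p-values are too small.

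The lists of pseudouridines fixed beforehand behaved like the annotation, with which they share 33 of 34 and 41 of 43 members. In limma all 34 members of the 18S list rose in deletion, mismatch and stop. In the 28S list all 43 rose in deletion and mismatch, and 38 rose and 2 fell in stop rate, of which 1 fell with library medians subtracted. Adjusted over the list alone, the counts were 34, 34 and 34 for the 18S list and 43, 43 and 38 for the 28S list. Relative to the general rise 32 members of the 18S list and 41 of the 28S list were higher in deletion, and 2 of the latter were lower. Other T in the tests below are T off the list and without the authors' annotation. Leaving out annotated positions was not in the plan, and the annotation may not be independent of these libraries. Nearly all other T also rose in deletion, 99.4% in 18S and 98.3% in 28S, so list members were not called more often (Fisher's exact p = 1 for each). With a rise of at least 1 point required, 94.1% of the 18S list and 44.7% of other 18S T passed (Fisher's exact p = 6.28e-09), and 97.7% and 57.2% in 28S (p = 5.36e-09). Stop calls separated the list from other T without that limit. They numbered 34 of 34 against 140 of 358 in 18S (Fisher's exact p = 1.4e-13). In 28S they numbered 38 of 43 against 271 of 684 (Fisher's exact p = 1.79e-10). Mismatch calls covered all list members, but also 73.8% of other T in 18S and 76.8% in 28S (Fisher's exact p = 8.31e-05 and 2.94e-05).

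3 list members without the annotation also rose, of which 18S 1046 and 28S 4532 directly follow annotated pseudouridines 18S 1045 and 28S 4531 in the same run of T. 18S 1046 had 12.1% ± 0.28 mismatch with CMC and 1.60% ± 0.078 without, and 28S 4532 had 12.7% ± 0.33 and 1.25% ± 0.052 (SD, n = 3). At 28S 4532 the stop rate reached 25.4% ± 1.2 against 3.42% ± 0.18 (SD, n = 3). 28S 4493 was the weakest, with 3.13% ± 0.025 against 1.47% ± 0.10 mismatch and 2.73% ± 0.083 against 0.033% ± 0.0096 deletion (SD, n = 3).

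The 7 other modified 18S positions, fixed as a contrast, went several ways. In deletion 4 rose and 3 fell, and relative to the general rise 1 was higher and 5 were lower. 18S 1248, which carries a methyl and an aminocarboxypropyl group besides being a pseudouridine, had 58.4% ± 0.66 mismatch without CMC and 56.2% ± 0.10 with it (SD, n = 3; limma adjusted p = 0.16), and 20.8% ± 0.99 and 18.2% ± 0.85 deletion (SD, n = 3; limma adjusted p = 0.011). Its stop rate rose from 1.38% ± 0.24 to 5.19% ± 0.41 (SD, n = 3; log2 change 1.85, limma adjusted p = 5.57e-06), and 4 of the 5 members tested for stop rose. Among these, 18S 1842 and 1832 had low CMC+ rates of 0.077% ± 0.047 and 0.263% ± 0.25 (SD, n = 3), near the added constant. 18S 1337 fell from 1.99% ± 0.31 to 1.46% ± 0.23 (SD, n = 3; limma adjusted p = 0.036). 18S 1639, a 7-methylguanosine, had 13.7% ± 1.1 deletion and 15.8% ± 0.65 mismatch without CMC, and its stop rate rose from 1.92% ± 0.22 to 12.8% ± 0.73 (SD, n = 3; limma adjusted p = 9.9e-08). 18S 1851, a dimethylated A, had 26.9% ± 0.90 mismatch without CMC and 29.2% ± 0.54 with it (SD, n = 3; limma adjusted p = 0.061). The acetylated cytidines 18S 1337 and 1842 had 0.666% ± 0.036 and 0.946% ± 0.15 deletion with CMC (SD, n = 3).

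Annotated pseudouridines were separated from the 1057 other T most fully by the mismatch rise, with an area under the ROC curve of 0.987, against 0.930 for deletion, 0.908 for stop, 0.926 for the largest stop rise at the position or up to 2 bases 5′ and 0.762 for single-base deletions (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The mismatch value was 0.982 in 18S and 0.990 in 28S. Of the 98 T with the greatest mismatch rise 80 were annotated, against 58 for deletion, 61 for single-base deletions, 47 for stop and 54 for the largest nearby stop. Deletion was taken at the base itself, whatever its place in a run. Differences between these areas were not tested, and the annotation may not be independent of these libraries. Across the 4383 positions called in both stop and deletion, the rises had Pearson's r = 0.48 and Spearman's rho = 0.31, and across the 98 annotated positions r = 0.027 and rho = 0.052, again across positions that are not independent replicates.

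The amplicons asked whether the same events are seen at single loci in RT-PCR products. In each amplicon the position with the highest CMC+ deletion share was a labelled one. In 18S rRNA, 35.5% of CMC+ reads (95% exact interval 35.5 to 35.6) and 0.268% of CMC- reads (0.265 to 0.270) had a deletion at 1045, and 22.0% (21.96 to 22.05) and 0.098% (0.096 to 0.099) at 1056. At EEF1A1 519 the shares were 2.68% (2.676 to 2.692) and 0.020% (0.0196 to 0.0210), and at MALAT1 5590 they were 11.04% (11.02 to 11.06) and 0.0064% (0.0060 to 0.0069). There was 1 library per condition, so these are differences between libraries with no replicate check.

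Mismatches also stood highest at a labelled position of each amplicon. They made up 11.2% of CMC+ and 0.410% of CMC- reads at 18S 1045, 3.13% and 0.272% at 1056, 2.97% and 0.197% at EEF1A1 519, and 12.7% and 0.102% at MALAT1 5590. Either event was present in 46.8%, 25.1%, 5.65% and 23.7% of CMC+ reads at these 4 positions and in 0.677%, 0.370%, 0.217% and 0.108% of CMC- reads. The surrounding sequences, 10 bases to each side, are AAGTCGGAGGTTCGAAGACGA for 18S 1045, TCGAAGACGATCAGATACCGT for 18S 1056, TTGTCGGTGTTAACAAAATGG for EEF1A1 519 and TTTAAAATTGTAGGACTTGTT for MALAT1 5590.

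18S 1045 and EEF1A1 519 each belong to a pair of T, within which a single-base deletion cannot be placed. The files put all such deletions on 1045 and none on 1046, and all on 519 and none on 518, so the 5′ base holds them in 18S rRNA and the 3′ base in EEF1A1. Mismatches do not have this ambiguity of identical bases, but whether alignment next to a deletion moved some of them was not tested. At 18S 1046 mismatches made up 7.64% of CMC+ and 0.268% of CMC- reads, and at EEF1A1 518 they made up 0.686% and 0.396%. MALAT1 5590 and 18S 1056 are lone T.

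The 3 next greatest deletion rises of each amplicon all lay to the 5′ side of a labelled position. 18S 1043, 1044 and 1055 had 19.7%, 12.9% and 6.03% with CMC and 0.168%, 0.035% and 0.022% without, and MALAT1 5589, 5588 and 5587 had 9.31%, 5.24% and 4.18% with CMC and 0.047%, 0.016% and 0.0024% without. EEF1A1 516, 515 and 506 had 2.17%, 1.44% and 0.907% with CMC and 0.061%, 0.042% and 0.0092% without, so the share at 516 came near the 2.68% at 519. Rises of at least 1 point were present at 12 positions of the 18S rRNA amplicon, 3 of EEF1A1 and 9 of MALAT1. For mismatch, 18S 1046 and MALAT1 5589, with 5.63% against 0.430%, were next, and no unlabelled EEF1A1 position rose by more than 0.453 points.

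**Figure D5:**
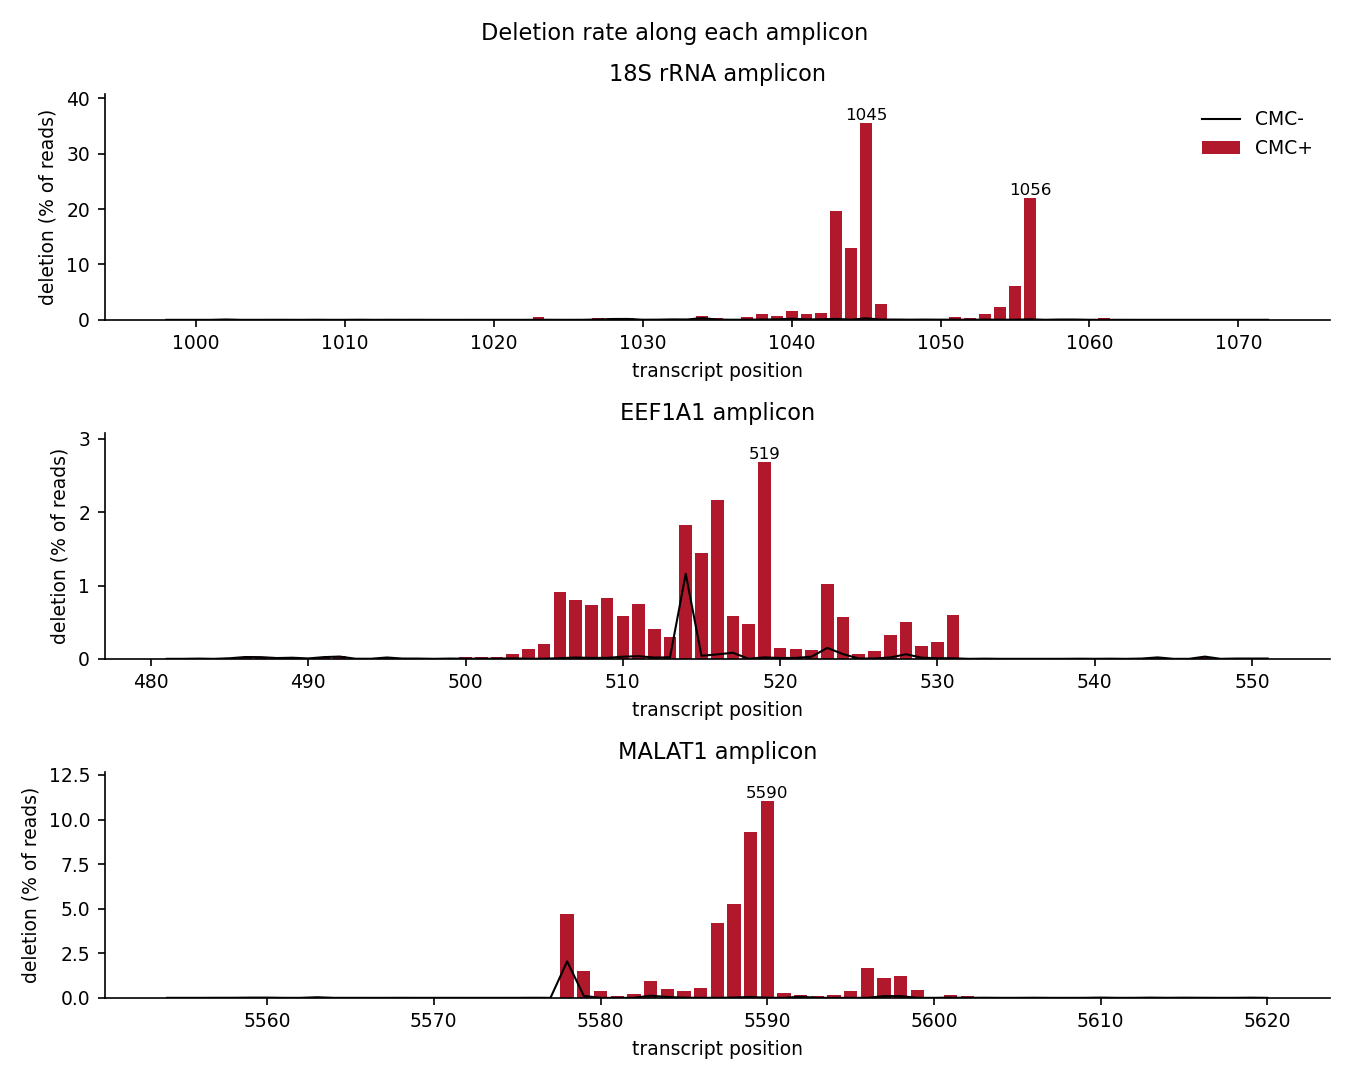
Deletion share (percent of reads) at each transcript position of the 18S rRNA, EEF1A1 and MALAT1 amplicons in the CMC+ library (bars) and the CMC- library (line), with labelled positions numbered. The labelled positions reach 35.5%, 22.0%, 2.68% and 11.04%, and there are no replicates and hence no error bars.

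18S 1045 and 1056 were covered by both library types, which were not normalised together. So was annotated pseudouridine 18S 1004, picked after its values were seen, whose signal was nearly absent from the amplicon. With CMC it had 0.0014% deletion and 0.094% mismatch there, against 5.60% ± 0.035 and 15.0% ± 0.11 in the transcript libraries, and 18S 1002 in its run had 0.101% deletion against 47.9% ± 0.82 (SD, n = 3). Without CMC, 1004 had 0.00049% deletion and 0.109% mismatch in the amplicon, and 1002 had 0.062% deletion. The amplicon spans 998 to 1072, and its primer positions are not given in the sources used here, so it is not known here whether bases near its ends are primer sequence. If they are, the bases read there do not come from the RNA. The low values at 1004 and 1002 thus do not show that the amplicon missed a pseudouridine. In the transcript libraries 1045 had 41.0% ± 0.89 deletion with CMC and 0.241% ± 0.0021 without (SD, n = 3; log2 odds ratio 8.16, SE 0.063, limma adjusted p = 4.68e-11). 1056 had 16.1% ± 0.33 and 0.104% ± 0.017 (SD, n = 3; log2 odds ratio 7.53, SE 0.12, limma adjusted p = 4.67e-10). The amplicon shares of 35.5% and 22.0% lay below the former and above the latter by more than the spread of the transcript libraries. Mismatch was lower in the amplicon at both positions, with 16.8% ± 0.099 (SD, n = 3) at 1056 in the transcript libraries and 3.13% in the amplicon, and 15.9% ± 0.087 (SD, n = 3) and 11.2% at 1045. Stop rates in the transcript libraries were 20.2% ± 0.49 against 2.59% ± 0.16 at 1045 and 4.67% ± 0.16 against 2.04% ± 0.026 at 1056 (SD, n = 3). In the authors' deposited tables the pooled CMC+ deletion reads numbered 32227 at 1045 and 17884 at 1056, against 44226 and 24940 summed over the 3 CMC+ libraries, and the stop differences were 17.6 and 2.63 percentage points.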

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

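The tests of explanations in this part were chosen after the patterns were seen. Insertions were not among the measurements compared in the report. At the annotated pseudouridines the median insertion rate was 0.875% ± 0.040 in CMC+ and 0.092% ± 0.0049 in CMC- libraries (SD, n = 3), so a signal stood above the control level. In limma insertions rose at 97 of the 98 positions and 1 was not called, but they also rose at 59.0% of all 6933 tested positions and 63.2% of other T (median log2 odds ratio 0.70 over all). With library medians subtracted, chosen after seeing the data, 91 annotated positions were higher and 2 lower, against 254 and 430 of 1054 other T. The greatest rise was at 18S 1625, where 9.44% ± 0.26 of CMC+ and 0.533% ± 0.035 of CMC- reads had an insertion (SD, n = 3; log2 odds ratio 4.28, limma adjusted p = 7.93e-10). That position also had 42.4% mismatch with CMC.

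Of the positions without annotation, 133 had a deletion rise of at least 10 points. A candidate explanation is that these deletions belong to an annotated pseudouridine and are placed in its run of bases or extend 1 to 4 bases 5′ of it. 97.7% of them, 130 positions, lay there, against 5.42% of all unannotated positions. Their median CMC- rate of 0.083% decides nothing about deletions present without CMC, because these positions were picked for a rise over CMC-. An unannotated modified uridine stays open for the remaining 3 positions, 18S 1230, 18S 1232 and 28S 4117, which all have a T on them or within 4 bases 3′, as do 55.3% of unannotated positions.

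Deletions rose with CMC at A, C and G as well. Deletions that reach out from annotated pseudouridines are argued against as the whole cause, because 4078 A, C and G positions over 20 bases from any of these had a median log2 odds ratio of 4.09. CMC left on uridine or guanosine may add to the rise, but 19 lone A and C with no T or G from 1 base 5′ to 3 bases 3′ still had a median of 3.83 for single-base deletions, from 0.032% to 0.490%. Other effects of the CMC treatment on RNA, or of the separate handling of the CMC+ libraries, were not tested. No biological explanation was tested, since both conditions were of the same cells.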

How the results depend on the processing

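Coverage minimums of 20 and 200 reads or none removed no position, so they say nothing about stability. The tallies of alternative values below still count them, which makes these tallies look more stable than they are. Added constants of 0.1 and 2, the quasi-binomial model and edgeR were not run for stops, whose table gives rates without counts. Library medians subtracted, at least 10000 reads, 20 end positions left out, single-base deletions only, stop constants of 0.02 and 0.5 points, the authors' annotation as a list, and other ways to take deletion at annotated positions were chosen after seeing the data. So was the limit of 1 point in the tests of the reference base. Of 272 alternative values of the main results, 248 kept their direction and side of the threshold or stayed near the main count, and 24 moved. Among the former, the T odds ratio for deletion went from 4.15 to 2.60 with library medians subtracted, that for mismatch from 2.52 to 1.25 for the base 1 position 5′, and deletion calls from 6625 to 4518 for sums over runs, which leave fewer units. A difference of at least 1 point, which is stricter by construction, lowered the calls to 2591 higher and 10 lower for deletion, 1610 and 344 for mismatch, and 949 and 714 for stop. With library medians subtracted the counts were 2281 and 2416 for deletion and 2367 and 2493 for mismatch. Positions lower in deletion numbered 22 with at least 10000 reads, 31 for single-base deletions and 22 for sums over runs, where fewer positions were tested. With the largest deletion rise in the run taken at annotated pseudouridines, the correlation with mismatch was 0.12 in place of -0.048, and 2 positions in place of 10 had high mismatch and low deletion. In the amplicons, deletions summed over the run gave 38.4% at 18S 1045 and 3.15% at EEF1A1 519. Summed with 1 base to each side they gave 51.4% at 1045, 28.1% at 1056, 3.30% at EEF1A1 519 and 20.6% at MALAT1 5590, in which a deletion of several bases is counted more than once. With the CMC- share subtracted they were 35.3% at 1045, 21.9% at 1056 and 2.66% at EEF1A1 519.

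Without each replicate in turn, the calls ranged from 6590 to 6611 higher and 48 to 62 lower for deletion, 3944 to 4208 and 854 to 1072 for mismatch, and 1916 to 2089 and 2122 to 2367 for stop. Of 777 alternative values of 45 changes at named sites, 775 kept direction and call, a tally that includes the coverage minimums that removed no position. The exceptions were 28S 4798, named in the report, and 18S 1247, whose deletion change of -1.25 became 0.98 for single-base deletions, and the cause was not tested. Deviations of CMC+ and CMC- libraries with equal replicate numbers correlated between -0.028 and 0.017 for deletion, -0.023 and 0.087 for mismatch, and -0.10 and -0.028 for stop. Not every library correlated best with its own number, but with 3 libraries per condition this cannot exclude that equal numbers were paired. With a replicate block, 6619 positions were higher and 58 lower for deletion, 4149 and 940 for mismatch, and 2089 and 2289 for stop.

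The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6682 positions for deletion, 5260 for mismatch and 4499 for stop, and the highest of the other splits called 0 for each, so 1 of the 10 splits gave as many. Small changes in deletion are the least well covered, as 14% of simulated changes of 1 on the log2 scale were called.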

Other observations

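The test of misread bases in this part was chosen after the pattern was seen. Some T positions far from any annotated pseudouridine also had many deletions with CMC. Among 633 T over 20 bases away, the median deletion rise was 1.22 points and 5 rose by at least 5 points. These positions were named after their values were seen. 28S 4117, in the sequence GGGCTCTCGCTTCTGGCGCCA from 4107 to 4127, had 18.5% ± 0.50 deletion with CMC and 0.050% ± 0.018 without (SD, n = 3; limma adjusted p = 5.97e-09). Its 3′ neighbour 28S 4118, also a T, had 9.46% ± 0.25 deletion and 7.64% ± 0.25 mismatch, against 0.023% ± 0.012 and 2.11% ± 0.11 without CMC (SD, n = 3). 18S 896 reached 8.50% ± 0.25, 28S 2384 7.49% ± 0.65 and 28S 391 5.76% ± 0.83 (SD, n = 3), with CMC- rates of 0.209%, 0.345% and 0.318%. Closer to an annotated site, 18S 1232, 6 bases 5′ of pseudouridine 1238, had 13.7% ± 0.62 deletion, with 15.0% mismatch against 0.771% without CMC.

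3 annotated pseudouridines rose by less than 5 points in deletion, mismatch and stop alike. They were 18S 119, with 0.874% ± 0.11 deletion and 2.30% ± 0.15 mismatch with CMC, 28S 4636, with 2.31% ± 0.078 and 6.10% ± 0.25, and 28S 5001, with 2.18% ± 0.11 and 2.74% ± 0.12 (SD, n = 3). Outside the labelled positions, MALAT1 5578 had 4.70% deletion with CMC and 2.04% without, and EEF1A1 514 had 1.82% and 1.16%, both from 1 library per condition.

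The base read in place of an annotated pseudouridine with CMC often equalled the 3′ neighbour. Of 70 positions whose 3′ neighbour is not T, 48 were misread mainly as that base, 14 of 25 before A, 20 of 23 before C and 14 of 22 before G, against 23.1 expected (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). A general preference of the enzyme or the sequencing may account for this at rRNA positions. The share was 57.1% at these positions without CMC (95% exact interval 44.7 to 68.9) against 68.6% with it (56.4 to 79.1). These intervals ignore that the same positions were scored in both conditions, and no paired test was run. At distant T the share was 68.7% without CMC and 72.6% with it. The mismatch rise 1 base 3′ was a median 0.072 of that at the site over 52 sites. This argues against a deletion read as a shift near a read end where more than 1 base follows the site. Where a read ends 1 base after the skipped site, no mismatch would follow, so the ratio cannot decide that case. The hypothesis that the neighbour is copied again over a CMC-modified base stays open, and 2 of 3 labelled amplicon positions with a 3′ neighbour other than T followed it, EEF1A1 519 and MALAT1 5590 with A making up 61.6% and 65.2% of mismatches, whereas at 18S 1056 C made up 43.1% and G 45.8%. Without CMC the neighbour's base made up 21.2%, 34.0% and 43.4% of mismatches at EEF1A1 519, MALAT1 5590 and 18S 1056. Its share was thus higher with CMC at EEF1A1 519 and MALAT1 5590 but not at 18S 1056. With 1 library per condition, this cannot exclude a preference present without CMC. A also made up 60.0% of mismatches with CMC at 18S 1045, whose 3′ neighbour is T, so a high share of A does not need an A neighbour and EEF1A1 519 and MALAT1 5590 are no evidence of copying.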
